A study of Mus musculus with 6 samples.

How the data were processed

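Gene expression was measured on Affymetrix arrays in lineage-negative, Kit-positive, Sca-1-positive bone marrow cells of young adult FVB/nJ mice, 3 samples given a control lentivirus and 3 given a lentivirus that carries HLX. Per the labels' protocols, cells were exposed to virus with 8 µg/ml polybrene in a serum-containing medium with mouse IL-3, IL-6 and stem cell factor, and GFP-positive cells were sorted after 2 days. RNA from 5000 to 10000 sorted cells was purified with a micro-scale column kit, 3 ng was amplified with the NuGEN Ovation Pico whole-transcriptome system, and the product was labelled with biotin. The labels do not say whether the numbered replicates came from separate mice or separate cultures, so p-values measure the spread between these samples, which may be partly technical.

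The deposited values are log2 expression levels, 1 per probeset and array, which the authors made with RMA and Affymetrix Power Tools, per the submitters' processing notes. The log2 scale was read from the range of the values on each array. RMA in general corrects background, normalizes between arrays and summarises the probes of a probeset, so differences common to most transcripts of an array are largely removed and weak signals compressed. The deposited distributions were close but not identical between arrays, with medians of 6.32 to 6.40. The software version and the genome build behind the probe annotation are not given in the sources used here, and no coordinates were used. The number of arrays, 3 per group, limits the precision.

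Of 35556 probesets, 21789 were paired with 1 gene symbol in the platform annotation, 1621 with several and 12146 were unlisted there and so are unnamed here. For 21698 of those with 1 symbol the gene identifier matched the RefSeq gene table of assembly GRCm38.p6, which was used for names alone, and 0 symbols needed an update. Probesets with 1 symbol were kept, and for the 999 genes with more than 1 probeset the one with the highest mean over all 6 arrays was taken, which left 19938 genes. No filter on dim probesets was applied.

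The comparison of HLX with control vector was fitted gene by gene on the log2 values with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, 2-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 4 residual degrees of freedom and an eBayes prior of 3.32. The SE given with a gene's log2 difference is the moderated SE of eBayes, in which its variance is drawn toward that of all genes. It can differ from the SE of the gene's own values. The level of Hlx was also compared by an exact permutation test. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 29 lists. Beside it stand camera with an estimated correlation and fry, which asks whether the members of a list differ on balance one way or, in its other form, in either direction. The 29 lists cover stem cell, lineage, cell cycle, metabolic, stress, signalling and contaminating cell type genes. They held 944 entries, of which 821 had a measured gene. Counts adjusted over the list alone use only the members of that list and are not adjusted across the 29 lists. Principal components and Pearson correlations between arrays were described without a test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

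Genes are named by a rule. Hlx, Btg1 and 1 further gene were fixed by name, and the further one is not analysed here. Next come the 10 largest differences in each direction among genes past the adjusted threshold whose groups did not overlap. Where a direction had fewer, places were filled by the largest differences among genes at an unadjusted p under 0.01 without overlap. Symbols of predicted genes, clones, small RNAs and families of near-identical genes were counted but not named. From each list, up to 4 members with the smallest p were taken where the list passed and 2 where it did not. Some of these are not printed below. The groups, lists, tests, naming rule and alternatives were set before the data were examined, and any exception is marked.

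The same code was tested on simulated data, 20 data sets of 19938 genes with the spread of these arrays and 200 changed genes each. For HLX against control vector, limma at the adjusted threshold recovered 19.2% of genes changed 1.5-fold, 70.9% of those changed 2-fold, 97.6% of those changed 4-fold and 99.0% of those changed 8-fold, and 5.06% of calls were false. The simulated genes were independent of one another, which real genes are not. These shares hold for 200 changed genes, and with fewer the adjusted threshold is stricter and recovers less. In the real arrays Hlx, at 7.75-fold, missed it (adjusted p from limma 0.0782). A count of 0 calls therefore does not exclude changes of these sizes in fewer genes than were simulated, nor changes near 1.5-fold. The alternatives were filters on dim probesets, other normalizations, other variance priors, array weights, the mean of a gene's probesets, every probeset, the replicate number as a block, other thresholds, other set tests, lists without shared members, and each array left out in turn. No 2 arrays were near-duplicates, since the SD over genes of the difference between 2 arrays was 0.29 to 0.36.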

Results

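The series compared mouse bone marrow cells that received HLX, a homeobox transcription factor, with cells that received an empty vector. The cells were lineage-negative, Kit-positive and Sca-1-positive, the fraction of marrow that holds haematopoietic stem cells and early multipotent progenitors. Each group had 3 arrays, numbered 1 to 3 in the labels, and both vectors carried GFP for sorting. All 6 arrays were alike in their distribution, with median log2 levels between 6.32 and 6.40, and their pairwise correlations over 19938 genes were 0.980 to 0.987. Arrays of the same vector correlated on average at 0.984 and arrays of different vectors also at 0.984. The first principal component, with 27.8% of the variance, set control replicate 1 and HLX replicates 1 and 2 apart from the other 3 arrays. The second, with 21.1%, placed all 3 control arrays on one side of 0 and all 3 HLX arrays on the other.

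The study's stated aim was to find genes regulated when HLX is overexpressed in stem cells, and Hlx itself was examined first. Hlx was 7.75-fold higher with the HLX vector than with the control vector (95% interval from limma 5.02 to 12.0). Its log2 level was 7.30 ± 0.32 (SD, n = 3) with the control vector and 10.26 ± 0.50 (SD, n = 3) with the HLX vector. The lowest HLX array lay 4.34-fold above the highest control array, and no other gene tested differed by as much. The adjusted p from limma was 0.0782, which misses the 0.05 threshold, and the exact permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. With a trended and robust variance prior Hlx passed, at an adjusted p of 0.0377. Where the Hlx probes lie relative to the vector's insert is not given in the sources used here, so the signal may sum insert and endogenous transcript.

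The named genes were taken by size of difference among those at an unadjusted p under 0.01 whose groups did not overlap, with symbols the naming rule allows. Beside Hlx, the genes so taken as higher in HLX arrays came from several functions. Rnf217, which encodes a ubiquitin ligase, was 2.69-fold higher (log2 difference 1.43 ± 0.13, SE, n = 3 per group), with an adjusted p from limma of 0.0782. Clec4a1, a C-type lectin receptor of myeloid cells, was 2.58-fold higher (1.37 ± 0.34), and Kif1c, a kinesin motor, 2.23-fold higher (1.16 ± 0.17). Ccnd1, the gene of cyclin D1 that drives entry into the cell cycle, was 2.01-fold higher (1.01 ± 0.14), with log2 levels of 8.20 ± 0.20 and 9.21 ± 0.15 (SD, n = 3). The remaining genes of this group included Rbis, a ribosome biogenesis factor (1.09 ± 0.21), Msl2, a subunit of a histone acetyltransferase complex (1.01 ± 0.29) and Itpripl2 (0.92 ± 0.15). Insl6 was at a log2 level of 7.96 ± 0.45 with HLX against 6.96 ± 0.25 with control, and Nucb2 at 7.85 ± 0.32 against 6.85 ± 0.43 (SD, n = 3). Apart from Hlx and Rnf217, their adjusted p from limma ran from 0.470 for Ccnd1 to 0.932 for Msl2.

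Of the 10 genes taken in the same way as lower in HLX arrays, Ms4a3, Ctsg and Nkg7 were in the myeloid progenitor list and Dntt in the lymphoid list, and their number was not tested for enrichment. Ms4a3, a membrane protein of granulocyte and monocyte progenitors, was 3.38-fold lower (log2 difference -1.76 ± 0.46, SE, n = 3 per group). Ctsg, which encodes the granule protease cathepsin G, was 2.18-fold lower (-1.12 ± 0.13), and Serpinb1a, an inhibitor of such proteases, 2.07-fold lower (-1.05 ± 0.27). Nkg7, a granule membrane protein, was 2.57-fold lower (-1.36 ± 0.37), the chemokine gene Ccl3 2.13-fold lower (-1.09 ± 0.23), and Dntt, the terminal transferase of lymphoid progenitors, 1.95-fold lower (-0.96 ± 0.27). The actin-severing protein gene Scin (-1.22 ± 0.21), the G protein subunit gene Gng12 (-1.33 ± 0.34), Mctp1 (-1.18 ± 0.22) and Atp8b4 (-0.94 ± 0.20) completed the group. All 10 missed the adjusted threshold, with Ctsg nearest at an adjusted p from limma of 0.283. Btg1, an antiproliferative gene fixed by name, was 1.23-fold lower (-0.30 ± 0.13) and was not called.

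**Figure D1:**
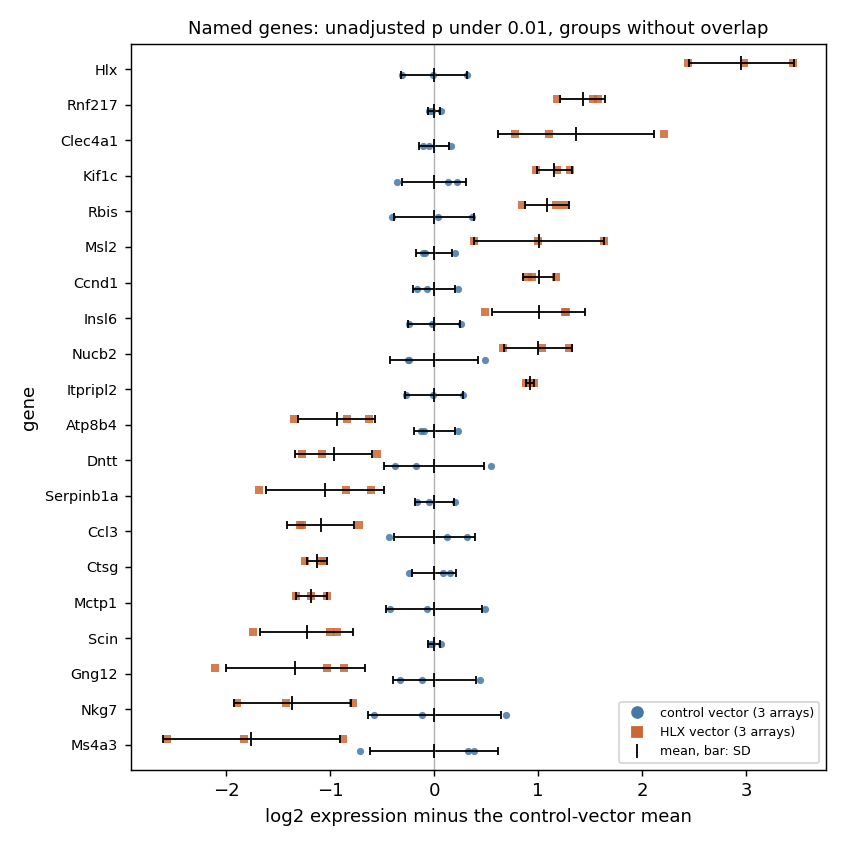
Log2 expression of Hlx and the other genes taken by size of difference at an unadjusted p under 0.01 without overlap, 1 gene per line, relative to the mean of the 3 control arrays; points are arrays, and the tick and bar are the mean and SD of 3 arrays. In every gene shown the 3 HLX arrays lie on one side of all 3 control arrays, from -1.76 for Ms4a3 to 2.95 for Hlx, and none of the genes passed the adjusted threshold.

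Across all 19938 genes, limma called 0 at an adjusted p under 0.05 and 2, Hlx and Rnf217, at an adjusted p under 0.10. At an unadjusted p under 0.05 there were 958 genes, 487 higher and 471 lower, where chance alone gives 997. Median centring of the arrays turned that split to 623 higher and 356 lower. The groups did not overlap in 1833 genes, 9.19% of those tested, and chance gives 10%. The median SD between replicates was 0.16 log2 units and the median absolute difference between groups 0.090. At an unadjusted p under 0.01 without overlap stood 209 genes, 109 higher and 100 lower, of which 12 were left unnamed under the rule on symbols. These were all the genes at that p, where chance alone gives 199, so the genes named by size came from a pool near the size chance gives.

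Among 29 gene lists, the stem cell list gave the clearest lower values. Of its 25 measured members 21 were lower with HLX, with a median log2 difference of -0.13 and a mean of -0.20. Mecom and Mllt3, both regulators of stem cell maintenance, were 1.76-fold and 1.59-fold lower (-0.81 ± 0.21 and -0.67 ± 0.15, SE, n = 3 per group), and Angpt1, a ligand of the receptor Tek, was 2.92-fold lower (-1.54 ± 0.46). Thy1, a surface glycoprotein of stem cells and T cells, went the other way at 1.68-fold higher (0.75 ± 0.16). Adjusted over the list alone, Thy1 was called higher and Mllt3 and Mecom lower, while over all genes tested 0 members passed. The list passed camera with the preset correlation (adjusted p = 0.0123), and with an estimated correlation it did not (unadjusted p = 0.113, adjusted p = 0.596). It also passed fry in either direction (adjusted p = 0.0279). The camera call was lost without control replicate 1 (adjusted p = 0.197) and without both arrays numbered 1 (adjusted p = 0.118), a choice made after the data were seen. It was also lost among genes above the median level of all probesets (adjusted p = 0.112), where lists have fewer members.

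Lymphoid genes were lower as well, with 21 of 28 measured members below 0 and a median log2 difference of -0.073. Flt3, the receptor of lymphoid and multipotent progenitors, was 1.60-fold lower (-0.68 ± 0.16), Cd79b, a B cell receptor subunit, 1.55-fold lower (-0.63 ± 0.21) and Dntt as above, whereas Cd7 was 2.59-fold higher (1.38 ± 0.51). None was called over all genes or adjusted over the list alone, where the smallest adjusted p was 0.103. The list passed camera (adjusted p = 0.0466) but not with an estimated correlation (unadjusted p = 0.0579, adjusted p = 0.562). The estimate, 0.0060, was below the preset 0.01, so a higher correlation between members does not account for that loss. It held without control replicate 2 or HLX replicate 3 and was lost without control replicate 1 or 3 or HLX replicate 1 or 2 (adjusted p 0.0797, 0.169, 0.250 and 0.0888).

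The G2/M and G1/S lists were both higher on balance with HLX. Of 38 measured G2/M and mitosis genes 28 were above 0, with a median log2 difference of 0.079, and the largest in evidence were the spindle gene Prc1 (0.38 ± 0.12), the mitotic kinase gene Plk1 (0.36 ± 0.13), Foxm1 (0.35 ± 0.15) and Kif20a (0.18 ± 0.091). No G2/M member was called adjusted over the list alone. Of 36 G1/S and DNA replication genes 23 were above 0, with a median of 0.043, and Ccnd1 alone was called adjusted over the list alone (adjusted p = 0.00425). Rfc5 (0.34 ± 0.16), Mcm5 (0.19 ± 0.089) and Cdc6 (0.29 ± 0.14), which act at the replication fork or in its licensing, followed it. Both lists passed camera (adjusted p = 0.00818 for G2/M and 0.0460 for G1/S). With an estimated correlation neither did (unadjusted p = 0.217 and 0.326, adjusted p = 0.596 and 0.664). The G2/M call was lost without HLX replicate 2 (adjusted p = 0.663) or control replicate 1 (0.0566), and the G1/S call without HLX replicate 1 or 2 or control replicate 2 or 3 (0.250, 0.498, 0.492 and 0.132).

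The lists of cholesterol synthesis, of ribosome biogenesis and of the stress response were also higher on balance, each by its own test. Of 20 cholesterol synthesis genes 14 were above 0 (median 0.13), among them Insig1, a regulator of sterol sensing (0.59 ± 0.14), and the enzyme genes Fdft1 (0.49 ± 0.19), Sqle (0.29 ± 0.11) and Sc5d (0.55 ± 0.24). Of 33 ribosome biogenesis and MYC-associated genes 26 were above 0 (median 0.070), with the spermidine synthase gene Srm at 0.49 ± 0.19, Polr1a, the large subunit of the ribosomal RNA polymerase, at 0.31 ± 0.16 and Mybbp1a at 0.30 ± 0.14, while Rrp12 was at -0.28 ± 0.12. Of 34 unfolded protein and integrated stress response genes 22 were above 0 (median 0.035), with the chaperone genes Hyou1 (0.55 ± 0.15) and Sdf2l1 (0.61 ± 0.19) and the transcription factor gene Cebpb (0.36 ± 0.12) higher and Ppp1r15a, a phosphatase subunit that ends the stress response, lower (-0.33 ± 0.095). No member of the 3 lists was called over all genes or adjusted over the list alone. The lists passed camera at adjusted p = 0.0167, 0.0278 and 0.0466 in that order. With an estimated correlation none of the 3 passed, with unadjusted p = 0.0581, 0.241 and 0.0455 and adjusted p = 0.562, 0.596 and 0.562. For the stress response list the estimate was -0.0081, below the preset 0.01, so a higher correlation does not account for its loss. The cholesterol call was lost without HLX replicate 1 or 2 or control replicate 3 (0.250, 0.0508 and 0.0760), and the ribosome biogenesis call without HLX replicate 1 or 2 or control replicate 2 or 3 (0.250, 0.198, 0.164 and 0.205). The stress response call held only without HLX replicate 3 among the 6 fits that left out 1 array, and adjusted p was 0.0735 to 0.263 in the others.

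NF-kB and inflammatory genes were higher on balance, 18 of 30, with members at both extremes. Tnf was 1.88-fold higher (0.91 ± 0.21) and Ccl3 2.13-fold lower, and both were called adjusted over the list alone (adjusted p = 0.0416 each). Tnip1 (0.31 ± 0.11), an inhibitor of the pathway, and Traf1 (0.36 ± 0.13) were above 0 without a call. The list passed camera (adjusted p = 0.0460) but not with an estimated correlation (unadjusted p = 0.217, adjusted p = 0.596). Of the 6 fits that left out 1 array the call held only without HLX replicate 2 (adjusted p = 0.00573), and adjusted p was 0.0645 to 0.250 in the others.

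Together 8 of the 29 lists passed camera with the preset correlation, 6 higher and 2 lower. With an estimated correlation 0 passed (smallest adjusted p = 0.562, 1 list at an unadjusted p under 0.05), and in fry's directional test 0 passed (smallest adjusted p = 0.499). For the lymphoid and stress response lists the estimate lay below the preset, so a higher correlation does not account for the loss of those calls. After cyclic loess or a repeated quantile normalization of the arrays 1 list passed, the stem cell list. In the deposited values the brightest 30% of genes had a median log2 difference of 0.022 against -0.018 for the other 70%. Without both arrays numbered 1, a choice made after the data were seen, 0 lists passed.

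Myeloid genes differed in both directions. In the progenitor and granule list 15 of 27 members were lower, with Ctsg called adjusted over the list alone (adjusted p = 0.00115), and the list's camera adjusted p was 0.0816. In the mature granulocyte and monocyte list 18 of 27 members were higher, with the lysozyme gene Lyz2 called adjusted over the list alone (1.63-fold, 0.70 ± 0.13, adjusted p = 0.0277) and the integrin gene Itgam at 1.85-fold (0.89 ± 0.22), and the camera adjusted p was 0.0816. With 1 array left out the progenitor list passed camera without control replicate 1 (adjusted p = 0.0173) or HLX replicate 2 (0.00573). The mature list passed camera without HLX replicate 1 (0.0321), and neither passed in the remaining such fits. In fry's test for differences in either direction both lists passed with all arrays, with an adjusted p of 0.0279 for the progenitor list and 0.0232 for the mature list. Leaving out 1 array ended this call of fry for the progenitor list except without HLX replicate 2 (adjusted p 0.0513 to 0.409 in the others) and for the mature list except without HLX replicate 1 (0.0550 to 0.537). The largest values came without control replicate 2.

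**Figure D2:**
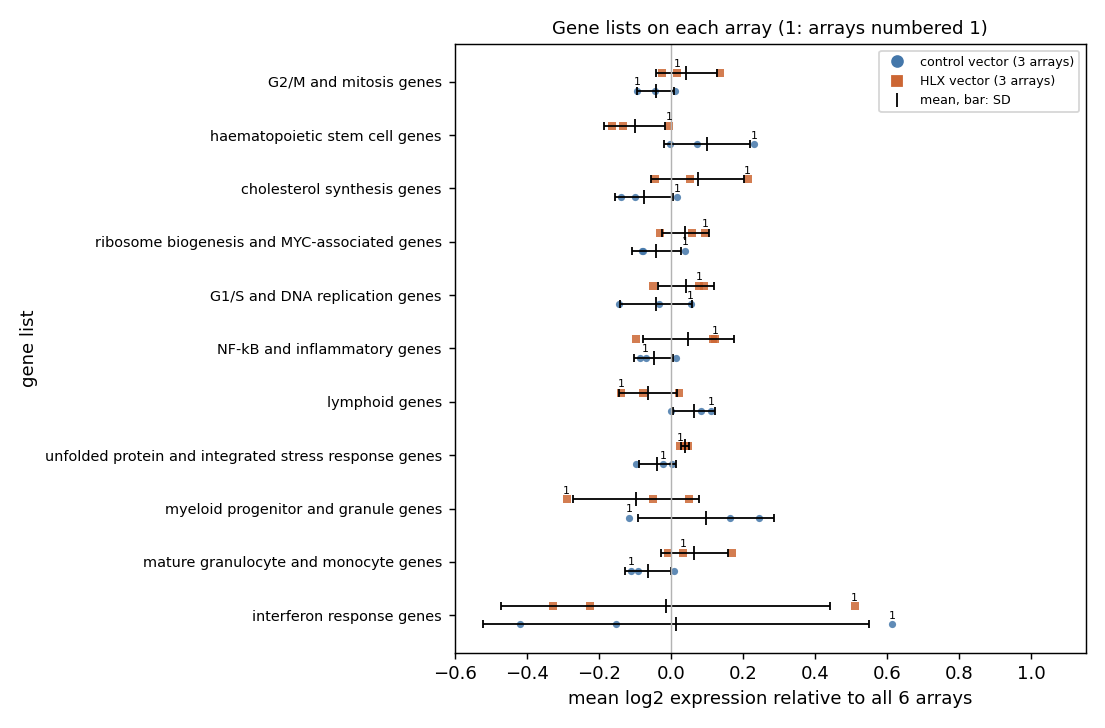
Mean log2 expression of 11 gene lists on each array, relative to the mean of all 6 arrays; points are arrays, the tick and bar are the mean and SD of 3 arrays, and "1" marks the arrays numbered 1 in each group. The stem cell list lies lower in HLX arrays than in control arrays by 0.20 on average, with HLX replicate 1 next to control replicate 2, and the interferon list is at 0.61 and 0.51 in the arrays numbered 1 and below 0 in the other 4.

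Among haematopoietic transcription factors Myb, needed by proliferating progenitors, was 1.45-fold lower (-0.54 ± 0.088, SE, n = 3 per group) and was called adjusted over the list alone (adjusted p = 0.0159), with Cebpb at 0.36 ± 0.12. In the glycolysis list the glucose transporter genes went opposite ways, Slc2a1 1.46-fold higher (0.55 ± 0.10) and Slc2a3 1.76-fold lower (-0.82 ± 0.19), and both were called adjusted over the list alone (adjusted p = 0.0157 and 0.0336). Over all genes Myb, Slc2a1 and Slc2a3 had adjusted p from limma of 0.662, 0.824 and 0.901. Neither list passed camera (adjusted p = 0.441 and 0.222). HOX cluster and TALE genes were mostly below 0, 20 of 28, led by Hoxb5 (-0.42 ± 0.13) and Hoxa7 (-0.19 ± 0.099), with a camera adjusted p of 0.101.

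The remaining lists had no member called adjusted over the list alone and no camera call. Among lineage lists, camera adjusted p was 0.568 for erythroid genes, led by Gata1 (0.27 ± 0.11) and Mfsd2b (-0.28 ± 0.15). It was 0.639 for mast cell and basophil genes, led by Srgn (-0.32 ± 0.11), and 0.785 for megakaryocyte and platelet genes, led by Mmrn1 (-0.26 ± 0.13). It was 0.590 for dendritic cell and MHC class II genes, with Siglech at -0.32 ± 0.10, and 0.417 for stromal, endothelial and osteoblast genes, with Fn1 at -0.36 ± 0.11 and Pecam1 at -0.34 ± 0.11. Among signalling lists it was 0.749 for cytokine receptors and signalling regulators, with Csf2rb2 at 0.40 ± 0.12, and 0.320 for PAK, RAC and cytoskeleton genes, with Was at 0.32 ± 0.11 and Diaph1 at -0.25 ± 0.11. It was 0.729 for AP-1 and immediate early genes, with Nr4a2 at -0.53 ± 0.16, 0.729 for p53 target and cell cycle arrest genes, with Rrm2b at -0.49 ± 0.16, and 0.377 for apoptosis genes, with Bcl2l1 at 0.46 ± 0.15. It was 0.377 for heat shock genes, led by Fkbp4 (0.21 ± 0.10), 0.785 for electron transport chain genes, led by Cyc1 (0.22 ± 0.099), and 0.790 for cytosolic ribosomal protein genes, led by Rplp2 (-0.20 ± 0.11). It was 0.705 for replication-dependent histone genes, led by H2bc9 (-0.29 ± 0.12), and 0.568 for sex-linked expression genes, led by Zfy1 (-0.17 ± 0.12). The median of the AP-1 and immediate early genes was -0.0018, while their mean was 0.025 and camera pointed up.

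Interferon response genes gave no camera call between vectors (adjusted p = 0.790) and stood apart in 1 array of each vector. Between vectors the smallest p in the list were those of Irf1 (0.45 ± 0.18) and Oasl1 (-0.28 ± 0.12). The list stood at 0.61 in control replicate 1 and 0.51 in HLX replicate 1, relative to the mean of all arrays, and between -0.42 and -0.15 in the other 4 arrays. Irf7, a regulator of the response, was 3.38-fold higher in the arrays numbered 1 than in the other 4, Oasl2 3.09-fold and Ifit1 2.99-fold, genes chosen after their values were seen. These are not typical of the list, whose median was 1.68-fold, and Rsad2 was at 1.08-fold. The list's direction turned with the array left out, up without control replicate 1 (adjusted p = 0.000883) and down without HLX replicate 1 (0.00453) or control replicate 2 (0.00805). With an estimated correlation, 0.582 to 0.795 between its members in these fits, none of the 6 gave a call (adjusted p 0.654 to 0.985), a test added after the result was seen.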

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

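Leaving out both arrays numbered 1 was chosen after the data were seen, and the other alternatives before. The count of genes at an adjusted p under 0.05 was 0 in limma as deposited and under every alternative fit except the trended and robust prior, where it was 1, Hlx (2.95 log2 units, adjusted p = 0.0377). It was 2 at an adjusted p under 0.10, and 182 genes (100 higher, 82 lower) met an unadjusted p under 0.05 with a 1.5-fold difference. At an unadjusted p under 0.05 alone the count was 958, and 606 among genes above the median level, 1573 over every probeset and 805 to 1269 with 1 array left out. The Hlx difference ran from 2.71 to 3.21 with 1 array left out. The 83 other genes taken by the naming rule, some of them not printed here, kept their direction in all 1396 refitted values. For genes whose groups did not overlap, leaving out 1 array cannot turn the direction, and other priors or a block leave the difference unchanged. The kept direction is therefore no sign of stability, and as none was called to begin with, neither is it that none entered. The count of gene lists, 8 as reported, was 10 with array weights (7 higher, 3 lower), 8 with the trended and robust prior, 7 with the mean of a gene's probesets, 6 above the 25th percentile of level and 6 with members of 1 list only. It was 0 for genes above the median level, 1 after repeated quantile normalization, 2 after median centring, 1 after cyclic loess, 0 with an estimated correlation, 0 with fry and 0 without both arrays numbered 1. With 1 array left out it was 2 to 8: 5 without control replicate 1 or 2, 2 without control replicate 3, 4 without HLX replicate 1, 3 without HLX replicate 2 and 8 without HLX replicate 3. Above the median level lists have fewer members, normalization is taken up among the other observations, and otherwise the cause was not tested. Calls kept under 11 settings of camera at the preset correlation, other than leaving out 1 array, were 9 for the stem cell list, 7 for G2/M, 6 each for cholesterol synthesis and ribosome biogenesis, 5 for G1/S, 4 each for lymphoid and NF-kB genes and 3 for the stress response, with 0 reversed. The estimated correlation and fry's directional test are outside these 11 and each kept 0 calls. The mean correlation within minus between vectors moved from 0.000267 to 0.00686 over the 1000 most variable genes, and the cause was not tested.

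With the replicate number as a block the count was 0 genes at the adjusted threshold (smallest adjusted p = 0.636, 1205 genes at an unadjusted p under 0.05) and 8 lists, in which the mature granulocyte and monocyte list entered (adjusted p = 0.0278) and the lymphoid list left. Deviations of same-numbered arrays from their group means correlated at 0.20, 0.0085 and 0.14, against -0.23 to 0.11 for pairs with different numbers. HLX replicate 2 correlated better with control replicate 1 (0.043) than with its own number, and the labels name no shared day, so the numbers were not taken to pair the arrays, though a link within number 1 or 3 is not excluded. The number of arrays, 3 per group, limits the precision, and signal over background is not analysed here.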

Other observations

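The comparison of dendritic cell genes, the tests of a level-dependent difference, the reading of macrophage genes by their level, the counts of splits at the adjusted threshold and in the either-direction test and the genes singled out in the first paragraphs were chosen after results were seen. The other tests were set before their own results. Those of the interferon and myeloid patterns were set after the patterns themselves were seen.

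Some genes of the myeloid and dendritic lists outside the naming rule had large differences, and they form no tested group. At an unadjusted p under 0.05 the progenitor list had 3 members higher and 6 lower, the mature list 3 higher and 1 lower, and the dendritic and MHC class II list 0 higher and 3 lower, Flt3, Siglech and Clec10a. Csf1r, the receptor of macrophage colony-stimulating factor, was 2.57-fold higher with HLX (log2 difference 1.36 ± 0.53, SE, n = 3 per group), with HLX arrays at 6.49, 7.80 and 8.92 against control arrays at 6.28, 6.48 and 6.37. Itgax, an integrin of dendritic cells and macrophages, was 2.28-fold higher (1.19 ± 0.52), Igsf6 1.92-fold (0.94 ± 0.39), the transcription factor gene Spi1 1.62-fold (0.70 ± 0.28) and Cd68 1.42-fold (0.51 ± 0.15). Mpo, the granule enzyme myeloperoxidase, was 2.23-fold lower (-1.16 ± 0.38), Fcer1g 1.57-fold lower (-0.65 ± 0.18) and Plac8 1.42-fold lower (-0.50 ± 0.17). Each missed the adjusted threshold of limma, with adjusted p of 0.914 or more.

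The microRNA gene Mir15a was 2.46-fold higher with HLX (log2 difference 1.30 ± 0.26, adjusted p from limma 0.839), with all 3 HLX arrays above all 3 control arrays. Mir16-1, its neighbour in the same primary transcript, was at 0.10 ± 0.12 and the host gene Dleu2 at -0.10 ± 0.13, both at low levels on the arrays. An array probeset over a short precursor does not measure the mature microRNA.

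Interferon genes were high in both arrays numbered 1: 25 of 35 measured members lay above the other 4 arrays in both, with a median of 1.68-fold over the list. Chance gives 6.67% per gene, but only for a pair of arrays named beforehand. This pair was picked after its values were seen, and the members are correlated (estimated at 0.703), so the count only describes the pattern. More dendritic cells in those arrays would raise dendritic and MHC class II genes, but that list was at -0.12 in control replicate 1 and -0.00077 in HLX replicate 1, relative to all arrays. A culture or array batch shared by the arrays numbered 1 stays open and may account for the pattern. The interferon list and genes correlated with its mean above 0.9 in either direction, 391 genes in all, were left out. Deviations of the arrays numbered 1 then still correlated at 0.131 over 19547 genes, above the highest of 6 pairs with different numbers (0.0804). Genes of the interferon response under that limit may have stayed in, so a pattern beyond interferon genes is not shown. The arrays numbered 3 correlated at 0.128 in the same genes and those numbered 2 at -0.014. Beyond dendritic cells no biological explanation was tested, since the design gives none for a replicate number.

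Among the myeloid lists 13 members had an unadjusted p under 0.05, 6 higher and 7 lower with HLX, with a median absolute log2 difference of 0.89. A large share of mature macrophages in the HLX samples is argued against. Of their abundant genes, 21 had a median log2 difference of 0.033 ± 0.016 (SE over genes, not arrays). This lay below a bound of 0.35, set before the test but with the rise of Lyz2 (0.70), already seen, as its reference. The 9 genes at low levels, C1qa, C1qb and C1qc included, were at 0.033 ± 0.017 (SE over genes, from -0.078 to 0.074). Only 6 of these 9 lay between the quartiles of gene level, and weak signals are compressed. The other 12, up to Fth1 at 12.07 in both groups, would hide a small share, so a small share is not excluded. Cells of the monocyte and macrophage line without those transcripts were not tested and stay open, with Hmox1 (0.37) and Lgals3 (0.30) highest of the 21 and Csf1r, Itgax, Cd68, Lyz2 and Itgam, outside that list, higher as well. A single deviating array cannot be told apart from an effect of HLX. The median difference fell to 80.4% (bootstrap SE over genes 9.96) without control replicate 2, which also ended both calls. Both calls ended as well without control replicate 1, control replicate 3 or HLX replicate 3, with the median at 84.8%, 110% and 84.3%. All 13 members kept their direction in every fit, but they were picked by their p in these same arrays. An effect of HLX on myeloid differentiation, the biological difference of the design, stays open and is a hypothesis.

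A level-dependent difference between arrays left in the deposited values may contribute to the 6 lists that were higher with HLX. Cyclic loess took the mean shift of their 191 members from 0.090 ± 0.016 to 0.074 ± 0.016 (SE over genes), 82.5% of its value (bootstrap SE over genes 3.80), and 0 of the 6 calls held. Every SE in this paragraph is taken over genes, which are not independent replicates, and does not measure the spread between arrays. The shift shrank in 5 of the lists but not in NF-kB genes (0.095 ± 0.067 before, 0.097 ± 0.067 after), whose call ended all the same (adjusted p = 0.114), and the cause of that was not tested. A level-dependent difference and an effect of HLX stay unresolved for these lists, at the 94.3 to 99.3 percentiles of 10000 random lists matched on level. The random lists were drawn gene by gene, so these percentiles leave out the correlation between members of a real list. For the stem cell list such a difference is argued against as the whole cause. Of its mean shift 97.7% (SE 5.10) remained, and its camera call held after loess (adjusted p = 0.0200) and quantile normalization (0.0160). The call did not hold without control replicate 1 (0.197) or among genes above the median level (0.112). An effect of HLX on this list is a hypothesis.

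The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. At the adjusted threshold limma called 0 genes in the real split and at most 1 in another, and with a real count of 0 all 10 splits are as large by definition, which tells nothing. At an unadjusted p under 0.05 the real split gave 958 genes and the highest other 2305, with 3 of 10 splits as large as the real one. For gene lists in camera the real split gave 8 and the highest other 10, and 2 of 10 were as large. For lists past fry in either direction, the stem cell and 2 myeloid lists, the real split gave 3 and the highest other 7, and again 2 of 10 were as large. The split with 2305 genes sets control replicate 1 and HLX replicates 1 and 2 against the others and points to a structure of the samples. Those 3 arrays had medians of 6.32 to 6.34 against 6.38 to 6.40, and in them the brightest 30% of genes were higher by a median of 0.075 and the other 70% lower (-0.083), with a Spearman correlation across genes, which are not independent replicates, of 0.288 between that difference and level.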
